A study of Triticum aestivum with 8 samples.

How the data were processed

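The series holds 8 arrays of bread wheat (Triticum aestivum) on a 2-colour Agilent oligonucleotide array, 2 arrays for each of 4 groups. Each array carried RNA of stressed developing seed in one dye and RNA of control seed of the same cultivar in the other dye, both taken 5 days after pollination per the labels. The groups were drought in Capelle Desprez, drought in Plainsman V, and heat and drought together in each of these cultivars. Per the labels, total RNA was extracted with RNAzol, and 1 µg was amplified and labelled through an amino allyl kit. The stressed RNA was in Cy5 on replicate 1 of every group and in Cy3 on replicate 2. The submitters' design text calls the replicates biological, with the dyes swapped between them. What each replicate pooled (plants, ears or pots) is not stated in the labels. The p-values therefore measure the spread between these arrays that is left after the dye term described below.

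The deposited spot intensity values are mean signals and median local backgrounds of the green (Cy3) and red (Cy5) channels, before any normalization, per the file headers. The processed intensity values in the same files were background-subtracted and dye-normalized by Feature Extraction, per the file headers. The deposited log10 ratio of red over green is the ratio of these processed signals, per the file headers. The flags for spots that are saturated, well above background or outliers are Feature Extraction's own, per the file headers. The headers give version 9.5.3.1, whereas the submitters' processing notes name version 10.1. The deposited series matrix holds log2 values of the authors with scale, centring and direction unstated. Set against the array files, each of its columns was red over green on the log2 scale, with slopes of 0.998 to 1 against the deposited log ratios and correlations of 0.869 to 0.997. These slopes were positive in both dye orientations, so the columns were not turned to a common direction. The column medians lay between -0.07 and 0.03. The direction of every ratio used here came from the dyes in the labels.

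Each array had 15744 spots, of which 536 were control spots and were left out of the tests. The other 15208 spots held 15030 different probes of 50 to 60 bases, with 169 probes on 2 spots and 3 probes on 4 spots. Backgrounds were corrected by normexp with an offset of 50, and log ratios were normalized within each array by loess, with control and outlier spots at weight 0. Outlier spots were removed, saturated spots were kept, and spots of 1 probe were averaged. Removing outliers left 216 probes without a value on some array. A probe was tested if it was well above background in at least 1 channel on at least 2 arrays, which 13701 probes met. Both conditions left 13486 probes tested. Every array was turned to stressed minus control. Computations used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and plots were drawn with matplotlib 3.10.9.

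All 8 arrays entered 1 limma fit with a mean for each of the 4 groups and a dye term for each probe, which left 3 residual degrees of freedom (prior 3.11). Contrasts were the response of each group, the mean response to each stress over both cultivars, heat and drought minus drought, and Capelle Desprez minus Plainsman V. Tests were two-sided and moderated, and p-values were adjusted over the tested probes by Benjamini-Hochberg with a threshold of 0.05. Standard errors (SE) are those of the limma fit. Correlations over probes describe pairs of arrays or effects, since probes are not independent replicates. The cultivar difference within each stress was a further contrast of the same fit, chosen after the data were examined.

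The dye orientation coincides with the replicate number in all groups, so the dye term is also a block on the replicate number. For a response tested against 0, the error thus leaves out what equally numbered arrays share, which can include differences between the replicate sets. Deviations from the group means of equally numbered arrays correlated at 0.43 to 0.79 over probes in all 6 pairs of groups. The numbers therefore pair the arrays. Equally numbered arrays share a dye orientation and, in part, a slide, and what made them deviate together was not separated. The dye term passed the threshold for 2406 probes, with an SD of 0.24 on the log2 scale. Slide 1 held replicate 1 of the drought groups, slide 2 held replicate 1 of the heat and drought groups, and slide 3 held replicate 2 of all 4 groups. A slide effect and the dye effect therefore cannot be fully separated. Each group lies on 2 slides, and slide entered an alternative as a random block.

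The files pair no probe with a gene: the description reads Unknown at every non-control spot, and 0 spots have another text. The gene table given for wheat lists no probe of this array. The 19 gene lists fixed before the data were examined (heat shock proteins, dehydrins, storage proteins, starch synthesis and others) therefore matched 0 probes, and their tests were not run. Probes are named by their identifier and sequence. The rule, fixed before the data were examined, takes at most 2 probes per direction and comparison, those with the largest log2 fold among probes past the threshold with the same sign on every array of the comparison, or, for the 2 differences, past the threshold. A probe that was not well above background on any array of a group in the channel of the stressed or the control RNA has only a bound there. The bound sets the mean of the brighter channel against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. It uses per-channel values after loess and Aquantile normalization, and each group holds both dye orientations equally.

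The test was tried on simulated log ratios for the 13486 probes, with the fitted residual SDs and dye terms and 200 changed probes in each of the 8 comparisons. Of changes of 1 on the log2 scale, 59.2 to 86.5% were recovered. Of changes of 2, 83.9 to 100% were recovered, and of changes of 0.5, 8.11 to 46.4%. At most 8.6% of the calls were false, and 0 had the wrong sign. The simulated spread had no slide effects. The number of arrays limits the precision of every value.

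Alternatives fixed beforehand were Feature Extraction's processed signals, median centring, scale normalization between arrays, no filter on dim probes, a filter on all 8 arrays, no dye term, slide as a random block, the series matrix values, and leaving out each array. Alternatives added after the data were examined were log ratios corrected for probe GC content, fits on the 4 arrays of 1 stress, slide as a fixed block, and the heat and drought arrays scaled to 1 spread.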

Results

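The series measured how the RNA of young wheat grains changed under drought and under heat combined with drought, in the cultivars Capelle Desprez and Plainsman V. Its title names heat and drought sensitivity of early grain development as the subject. In all, 8 grain samples of stressed plants, 2 per cultivar and stress, were each set against control grain of the same cultivar on 1 array, at 5 days after pollination. No array carried heat alone, so the contribution of heat was read only as the difference between the combined stress and drought. Median spot signals ranged from 751 to 1310 in green and from 912 to 1550 in red, against median backgrounds of 64 to 114 and 58 to 68. Between 73.8 and 84% of the spots were well above background in green and 78.1 to 90.5% in red. Up to 1.5% of spots were saturated in green and up to 4.2% in red. The arrays' own probe identifiers stand for the transcripts, since the files name no genes.

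Drought alone moved few transcripts by much. Averaged over both cultivars, 713 of 13486 probes rose and 531 fell at an adjusted p under 0.05, and 88 of these 1244 changed at least 2-fold. The highest fitted rise was at probe 65202 (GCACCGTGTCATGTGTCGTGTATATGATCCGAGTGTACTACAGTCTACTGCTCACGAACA), which rose by 2.76 ± 0.10 on the log2 scale (SE, n = 4 arrays, limma adjusted p = 0.0014). It rose on all 4 drought arrays, by 2.52 to 3.23, and its control channel was well above background on 1 of the 4, with only a bound in Plainsman V. Probe 128047 (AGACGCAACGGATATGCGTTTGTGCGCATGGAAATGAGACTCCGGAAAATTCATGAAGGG) rose by 2.30 ± 0.19 (limma adjusted p = 0.0046), with its control channel well above background on 2 of the 4 arrays and only a bound in Capelle Desprez (at least 4.87-fold). Probe 111283 (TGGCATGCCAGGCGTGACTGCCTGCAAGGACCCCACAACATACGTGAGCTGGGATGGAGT) fell by 1.55 ± 0.22 (limma adjusted p = 0.016), and its stressed channel was well above background on 1 of the 4, with only a bound in Capelle Desprez. These 3 averages are fitted values over a measured and a bounded cultivar. Probe 63524 (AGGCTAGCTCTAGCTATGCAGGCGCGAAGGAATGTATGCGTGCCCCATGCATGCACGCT) fell by 1.53 ± 0.17 (limma adjusted p = 0.0085), more in Capelle Desprez (-2.32) than in Plainsman V (-0.73), though the adjusted p of that cultivar difference was 0.43.

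The number of drought calls depended on the processing and on single arrays. It was 2554 after scale normalization between arrays, 3519 from the 4 drought arrays alone and 672 from Feature Extraction's processed signals. With slide as a random block (correlation 0.46 within a slide), 95 probes rose and 49 fell, all of them among the 1244, and without the dye term 169 rose and 93 fell, 262 in all. With the slide block probes 111283 and 63524 had limma adjusted p values of 0.081 and 0.06, whereas probes 65202 and 128047 stayed past the threshold. Without Plainsman V drought replicate 1 the count was 1 and without replicate 2 of that group it was 2. It was 541 and 136 without replicates 1 and 2 of Capelle Desprez drought. Over all tested probes the log ratios of the replicates correlated at 0.03 in each cultivar, and the mean log ratios of replicates 1 and 2 had the same sign at 53% of the probes.

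Within single cultivars, drought raised 203 probes and lowered 124 in Capelle Desprez and raised 101 and lowered 79 in Plainsman V. Probe 65202 rose in both cultivars, by 2.93 ± 0.14 in Capelle Desprez (n = 2 arrays, 1 of them with the control channel well above background, limma adjusted p = 0.0078) and at least 5.44-fold in Plainsman V (n = 2, limma adjusted p = 0.017). In Capelle Desprez probe 161138 rose by 2.66 ± 0.20 (limma adjusted p = 0.017), probe 63524 fell by 2.32 ± 0.23 (limma adjusted p = 0.017), and probe 111283 fell at least 3.75-fold (limma adjusted p = 0.042). In Plainsman V probe 73528 rose by 2.55 ± 0.28 (limma adjusted p = 0.024), probe 137685 fell by 2.38 ± 0.30 (limma adjusted p = 0.029, stressed channel well above background on 1 of 2 arrays), and probe 141333 fell by 1.61 ± 0.22 (limma adjusted p = 0.037). The 2 lists shared 57 rising and 28 falling probes, where independent lists of these sizes would share 1.5 and 0.7, and 0 probes were called in opposite directions. The drought arrays of both cultivars lay together on slides 1 and 3, so part of that overlap can be a shared slide effect. For the cultivar difference under drought, limma called 0 probes, with 1021 at an unadjusted p under 0.05, and from the 4 drought arrays alone it called 356. The counts of drought calls fell to 52 in Capelle Desprez and 24 in Plainsman V without the dye term, and to 111 and 58 with slide as a random block. With that block 4 named drought results missed the threshold, the 2 averages given above and the others within single cultivars. From Feature Extraction's processed signals they were 67 and 0 (2322 at an unadjusted p under 0.05 in Plainsman V), after scale normalization between arrays 942 and 1251, and from the drought arrays alone 2269 and 1888. The Capelle Desprez count was 1 without its replicate 2 or either Plainsman V drought array and 11 without its replicate 1, and the Plainsman V count was 0 without either of its own arrays (limma, 758 and 1050 unadjusted).

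**Figure D1:**
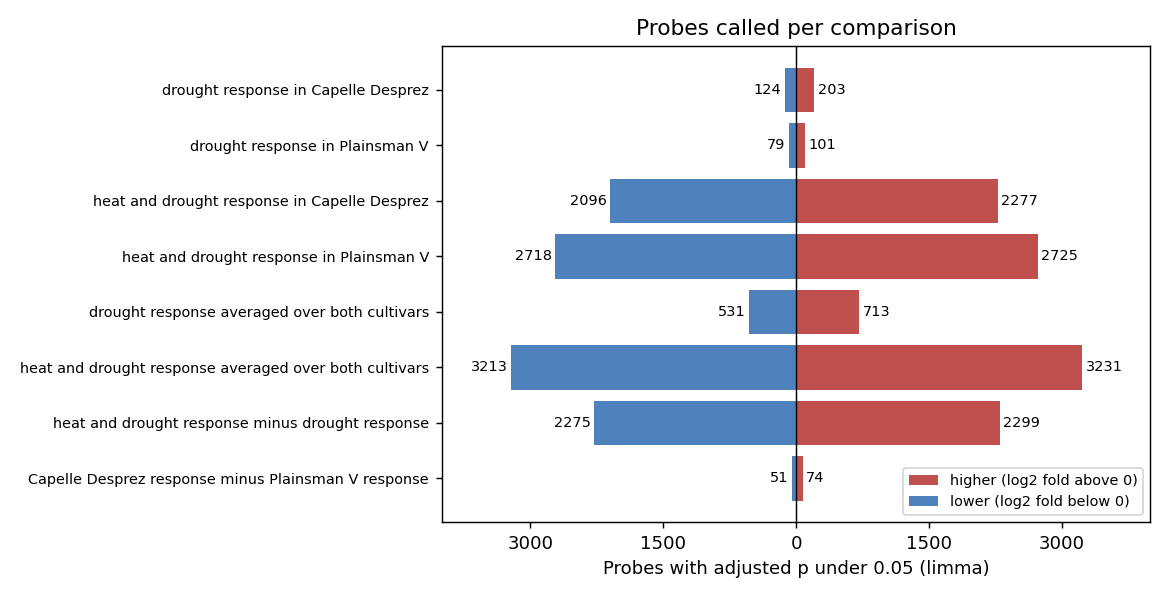
Bars give the number of probes with an adjusted p under 0.05 in each of the 8 comparisons (horizontal axis, probes), to the right where the log2 fold was above 0 and to the left where it was below 0. Drought averaged over both cultivars called 713 and 531 probes, and heat and drought together called 3231 and 3213.

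Heat and drought together changed many more transcripts than drought, and by more. Averaged over both cultivars, 3231 probes rose and 3213 fell, 47.8% of those tested, and 1283 of them changed at least 2-fold. Probe 52054 (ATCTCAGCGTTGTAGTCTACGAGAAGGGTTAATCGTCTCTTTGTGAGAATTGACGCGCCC) rose by 6.59 ± 0.22 on the log2 scale (SE, n = 4 arrays, limma adjusted p = 1.1e-05), from 4.54 to 8.11 across the arrays. Its control channel was well above background on 3 of the 4. Probe 175606 (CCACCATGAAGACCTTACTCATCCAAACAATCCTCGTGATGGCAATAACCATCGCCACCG) rose by 6.41 ± 0.14 (limma adjusted p = 3e-06), and its stressed channel was saturated on 1 of the 4 arrays. Probe 1803 (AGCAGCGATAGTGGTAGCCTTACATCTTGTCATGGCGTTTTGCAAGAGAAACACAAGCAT) fell by 6.03 ± 0.18 (limma adjusted p = 8.4e-06), and its stressed channel was still well above background on 2 of the 4 arrays. Probe 31585 (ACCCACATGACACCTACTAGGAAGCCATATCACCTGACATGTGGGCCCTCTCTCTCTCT) fell by 5.27 ± 0.09 (limma adjusted p = 2e-06) and was well above background in both channels of all 4 arrays. Log ratios of the replicates correlated at 0.69 over probes in Capelle Desprez and at 0.77 in Plainsman V. The count was 4847 with slide as a random block and 4811 without the dye term. Median centring in place of loess gave 2732 rises and 3687 falls, so the even split depends on the normalization.

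In Capelle Desprez 2277 probes rose and 2096 fell, and in Plainsman V 2725 rose and 2718 fell. In Capelle Desprez probe 54728 had the highest fitted rise, 7.01 ± 0.26 (n = 2 arrays, limma adjusted p = 4.8e-05), followed by probe 307303 with 6.59 ± 0.12 (limma adjusted p = 2e-05). Probe 147223 was saturated in the stressed channel on both arrays there and has only a bound (at least 55.6-fold). Probe 1803 fell by 5.92 ± 0.26 there (limma adjusted p = 7.3e-05) and probe 31585 fell by 5.60 ± 0.13 (limma adjusted p = 2.5e-05). In Plainsman V probe 52054 rose by 7.88 ± 0.32 (n = 2, limma adjusted p = 3.8e-05) and probe 62458 by 7.27 ± 0.17 (limma adjusted p = 1.1e-05). In that cultivar probe 1803 fell by 6.15 ± 0.26 (limma adjusted p = 4e-05) and probe 244880 fell by 5.97 ± 0.27 (limma adjusted p = 5.1e-05). The stressed channel of probe 1803 was well above background on 1 of 2 arrays in each cultivar, as was that of probe 244880 and the control channel of probe 52054 in Plainsman V. Both cultivars shared 1690 rising and 1579 falling probes, where independent lists would share 460.1 and 422.4, and 74 probes were called in opposite directions. The log2 folds correlated at 0.82 over probes. The arrays of both cultivars shared slides, so part of the shared calls can come from them. With median centring in place of loess 2171 probes rose and 3274 fell in Plainsman V. Without the dye term 2583 probes passed in Capelle Desprez, and after scale normalization 3361 passed in Plainsman V. Leaving out its own replicate 1 or 2 left 2134 or 1409 there, and 2836 or 3192 in Plainsman V.

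**Figure D2:**
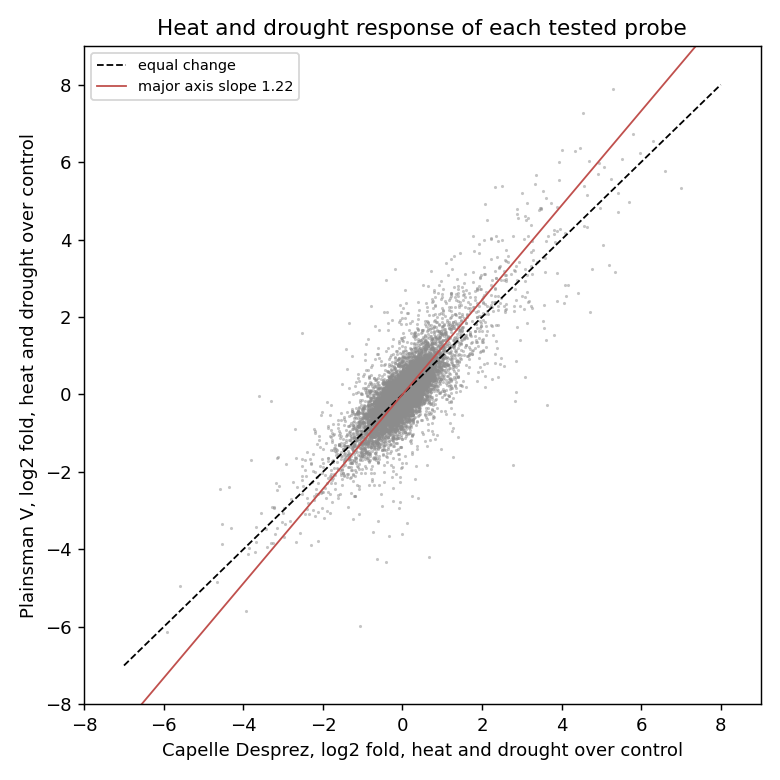
Each point is 1 of the 13486 tested probes, with its log2 fold of heat and drought over control in Capelle Desprez (horizontal) and in Plainsman V (vertical). The major axis of the points has a slope of 1.22 (solid line), against the line of equal change (dashed), and the correlation is 0.82.

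The combined stress was set against drought to see what it changed beyond drought. Of the tested probes, 2299 responded more positively to heat and drought than to drought, and 2275 more negatively, 33.9% in all. With median centring in place of loess these were 1810 and 2670. Probe 147223 (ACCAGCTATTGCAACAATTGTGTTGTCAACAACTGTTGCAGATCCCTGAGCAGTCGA) had the highest fitted difference, 7.25 ± 0.40 on the log2 scale (n = 8 arrays, limma adjusted p = 0.00016). Its size was not measured, because its stressed channel was saturated on both heat and drought arrays of Capelle Desprez. Under heat and drought it rose at least 55.6-fold in Capelle Desprez and by 6.74 in Plainsman V, and its values under drought were -0.52 and -1.45. Probe 52054 followed with a fitted difference of 6.77 ± 0.32 (limma adjusted p = 9.9e-05), though it was not well above background in either channel under drought in Plainsman V. The lowest fitted differences were -6.09 ± 0.26 at probe 1803 and -4.71 ± 0.20 at probe 103714 (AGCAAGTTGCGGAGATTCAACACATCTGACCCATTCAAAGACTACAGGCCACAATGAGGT), both with a limma adjusted p of 7.6e-05. Probe 103714 fell at least 11.4-fold under heat and drought in Capelle Desprez and fell by 5.60 in Plainsman V, where its stressed channel was well above background on 1 of 2 arrays. Only slide 3 held both stresses. There the differences were 7.01 at probe 147223, 7.41 at probe 52054, -6.64 at probe 1803 and -4.60 at probe 103714. Between slides 1 and 2 they were 7.49, 6.13, -5.54 and -4.81. The differences from slides 1 and 2 and from slide 3 correlated at 0.79 over probes. The count was 2784 without the dye term, 4518 with slide as a random block and 4936 with slide as a fixed block. It was 2694 and 2799 without replicates 1 and 2 of Plainsman V drought.

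Responses to the stresses overlapped in part. Of the 713 probes that rose under drought, 359 also rose under heat and drought, and of the 531 that fell, 357 also fell, where independent lists would share 170.8 and 126.5. Probes 65202, 128047 and 73528 rose under both stresses. Probe 63524 fell under drought averaged over both cultivars and rose under heat and drought, by 2.61 in Capelle Desprez and 3.08 in Plainsman V. Its fall in Plainsman V alone (-0.73) did not pass (limma adjusted p = 0.19). In Capelle Desprez its control channel averaged 13.42 on the drought arrays and 10.50 on the heat and drought arrays, and its stressed channel 11.10 and 13.11. The reversal there thus includes a change of the control channel. Probe 63524 was 1 of 65 probes that went this way, and 162 went the opposite way. Since 3231 probes rose and 3213 fell under heat and drought, independent lists would give opposite directions nearly as often as shared ones. Neither 65 nor 162 lies above that. Log2 folds of the 2 stresses correlated at 0.17 over probes in Capelle Desprez and 0.31 in Plainsman V, with covariances of 0.0347 and 0.0692. The labels do not say whether the arrays of both stresses carried the same control RNA. If they did, simulated unchanged groups would give a correlation of 0.5 and a covariance of 0.0159. The simulated spread left out what the dye term takes up, which equally numbered arrays share, so that covariance can be too low. Arrays of different replicates have different controls if each replicate had its own. Between drought and heat and drought arrays of different replicates, the log ratios correlated at 0.04 and -0.07 in Capelle Desprez and at 0.10 and 0 in Plainsman V. With equal replicate numbers the 2 stresses correlated at 0.28 and 0.20 in Capelle Desprez and at 0.40 and 0.33 in Plainsman V. Arrays of different replicates also differ in dye orientation and slide. Most of the correlation over all probes, and part of the overlap, may therefore come from shared controls, dyes or slides.

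**Figure D3:**
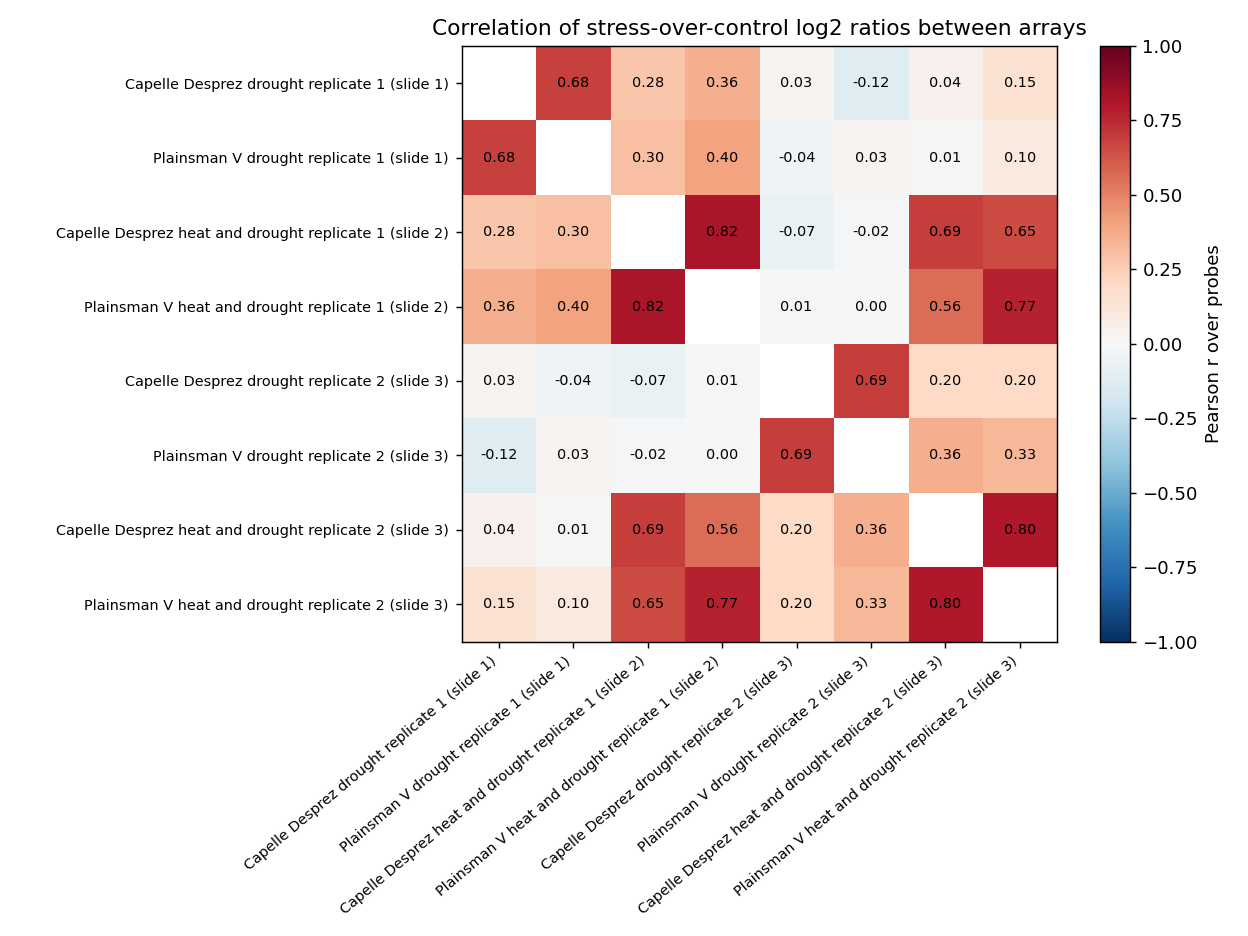
Each cell gives the Pearson correlation over 13486 probes (colour scale, -1 to 1) between the stressed-over-control log2 ratios of 2 arrays, ordered by replicate and named with their slide. Drought arrays of different cultivars on 1 slide correlated at 0.68 and 0.69, and drought arrays of 1 cultivar on different slides at 0.03.

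The cultivars were compared directly through the difference of their responses. Averaged over both stresses, 74 probes had a higher response in Capelle Desprez and 51 a higher response in Plainsman V. Probe 137685 (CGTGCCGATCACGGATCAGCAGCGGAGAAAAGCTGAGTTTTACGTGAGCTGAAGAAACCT) passed the test of the difference (n = 8 arrays, limma adjusted p = 0.024), but its size cannot be given because not every group measured it. It fell at least 19.7-fold under heat and drought in Plainsman V, and in Capelle Desprez neither channel was well above background under that stress. Probe 68602 (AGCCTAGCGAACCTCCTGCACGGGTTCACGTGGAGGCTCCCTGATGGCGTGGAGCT) had a difference of 2.77 ± 0.35 on the log2 scale (limma adjusted p = 0.037). It fell by 4.20 under heat and drought in Plainsman V and had 0.66 in Capelle Desprez (limma adjusted p = 0.21). Probe 30515 (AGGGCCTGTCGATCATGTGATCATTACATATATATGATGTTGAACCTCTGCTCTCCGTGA) also passed the test (limma adjusted p = 0.022). It fell by 3.60 under heat and drought in Capelle Desprez and was not well above background on any Plainsman V array, so no difference between the cultivars was measured. Probe 229750 (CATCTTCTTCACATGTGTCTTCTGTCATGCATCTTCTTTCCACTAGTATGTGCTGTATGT) had a difference of -1.96 ± 0.14 (limma adjusted p = 0.011). Under heat and drought it fell by 2.52 in Capelle Desprez and rose by 1.58 in Plainsman V, well above background in both channels of all 8 arrays.

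Under heat and drought, 351 probes had a higher and 329 a lower response in Capelle Desprez, 680 in all. The fitted log2 folds had the same sign in both cultivars at 451 of these and opposite signs at 229, of which 69 passed in both cultivars. The larger fitted change was in Plainsman V at 522. The cultivar differences on slide 2 and slide 3 correlated at 0.67 over probes. The 125 calls of the average difference became 465 with slide as a random block, 493 with slide as a fixed block, 194 with median centring and 26 without the dye term. They became 0 from Feature Extraction's processed signals (limma, 2066 at an unadjusted p under 0.05) and 0 after scale normalization between arrays (1685 unadjusted). Leaving out single arrays gave 0 to 37 calls, with 0 without either Plainsman V drought array (limma, 1329 and 1325 unadjusted) or replicate 2 of Capelle Desprez heat and drought (1758 unadjusted). The 680 calls under heat and drought became 246 from the processed signals, 51 after scale normalization, 236 without the dye term, 1341 with slide as a random block and 1538 with slide as a fixed block, both of which included all 680. They became 154 and 109 without replicates 1 and 2 of Capelle Desprez heat and drought, 112 and 133 without those of Plainsman V, and 160 without either Plainsman V drought array.

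**Figure D4:**
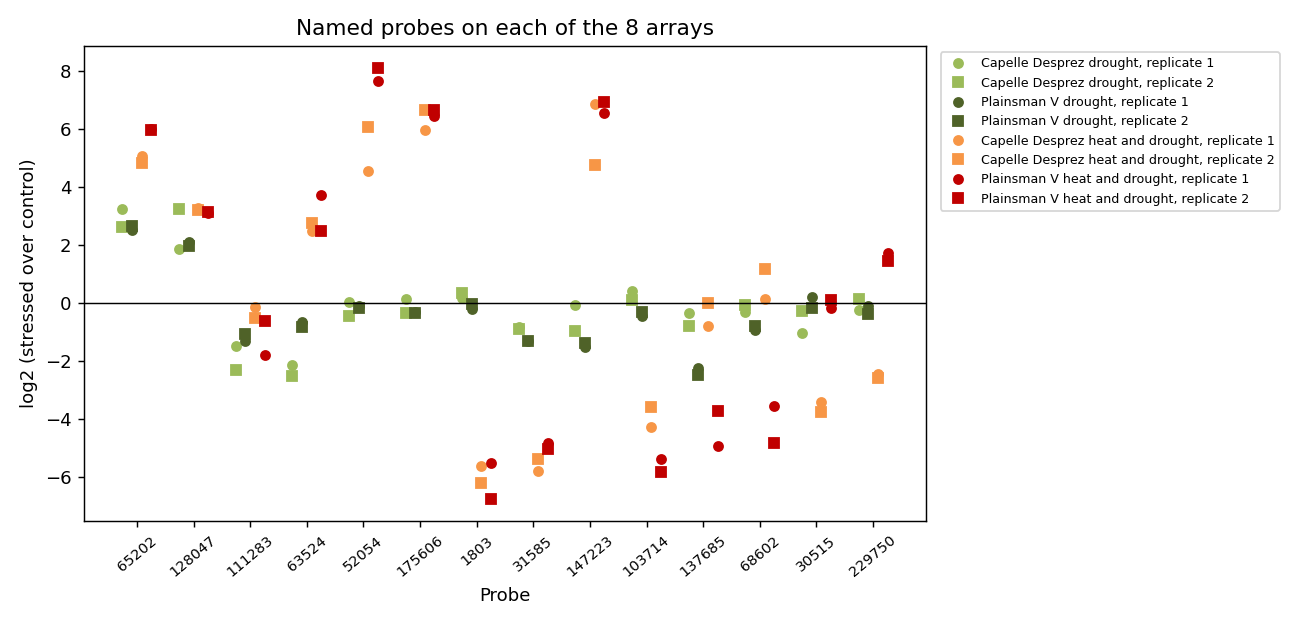
Points give the log2 ratio of stressed over control (vertical axis) on each of the 8 arrays for the probes named in the averaged comparisons and the differences, coloured by group and with circles for replicate 1 and squares for replicate 2. Probe 65202 lies between 2.52 and 3.23 on the 4 drought arrays, and probe 1803 between -6.77 and -5.53 on the 4 heat and drought arrays.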

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

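The slide test, the test of uniform compression and the counts of other splits in this part were chosen after the results they bear on had been seen, as was the test of signal near background, and the test of dim or saturated spots was written down before. The contrast between the cultivars under heat and drought was itself added after the data were examined.

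Responses of the cultivars differed by a test of the difference itself for 125 probes averaged over both stresses and for 680 probes under heat and drought. The named probes among these, as Capelle Desprez minus Plainsman V under heat and drought on the log2 scale, were 65202 (-1.03), 161138 (-1.76), 137685 (3.92), 307303 (0.81), 52054 (-2.57), 62458 (-2.73), 244880 (4.90), 103714 (1.67), 68602 (4.86), 30515 (-3.55) and 229750 (-4.11). Averaged over both stresses, the differences were 2.86 at probe 137685, 2.77 at probe 68602, -2.12 at probe 30515 and -1.96 at probe 229750. These are fitted values. The averages of probes 137685 and 30515 are no measured sizes, nor are the values of 4 of the probes under heat and drought. In that stress probe 137685 had neither channel well above background in Capelle Desprez and only a bound in Plainsman V, probe 30515 had neither channel well above background in Plainsman V, and probes 244880 and 103714 had only bounds in Capelle Desprez (at least 1.57-fold and 11.4-fold). For several of these probes 1 cultivar had little signal in the control seeds as well. Probe 30515 averaged a log2 signal of 13.50 in the control channel of Capelle Desprez under heat and drought and 7.14 in that of Plainsman V, where it was not well above background. Probe 244880 averaged 7.87 and 13.81, and probe 68602 8.22 and 14.05. At probe 62458 the control channel under heat and drought averaged 11.51 in Capelle Desprez and 7.54 in Plainsman V, and the stressed channel 16.05 and 14.81. Its smaller rise in Capelle Desprez thus came with a higher control signal, which was 7.43 on the drought arrays of that cultivar. Of the 680 probes, 136 also differed between the control seeds of the cultivars, against 36.7 for independent lists, though both tests use the same control channels.

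Signal near background in 1 cultivar was weighed for the 680 differences as a set. Of these, 557 were well above background in both channels on both arrays of each cultivar. Calls made up 5.24% of the tested probes with that signal and 4.29% of the others, which argues against signal short of that flag as the cause of most of them. Such signal stays open as the cause for the other probes, such as 30515 and 244880. The flag does not show how far a probe could fall. Probe 68602 carried it with a control signal of 8.22 in Capelle Desprez, against 14.05 in Plainsman V. A low level in 1 cultivar therefore stays open for flagged probes as well. Uniform compression of the Capelle Desprez ratios was tested by multiplying them by the fitted slope, after which 502 of the 680 still passed and 594 passed in all. Of the 680, 434 passed with the 4 heat and drought arrays scaled to 1 spread (458 in all). Scale normalization of all 8 arrays left 51 of the 680. It also brings the drought arrays to the spread of the others, and the median size of these differences went from 1.08 to 0.78 with an SE of 0.15 and 0.16. Compression of the Capelle Desprez arrays alone is thus argued against as the cause of most of the calls. The fit on the 4 heat and drought arrays, with no drought array in it, called 896 probes and kept 602 of the 680. The folds there are those of the main fit, and only the error estimate changed, with 1 residual degree of freedom per probe. Fits on 4 arrays also called more probes elsewhere, such as 356 against 0 for the cultivar difference under drought. Keeping 602 is thus weak evidence against a scale difference between the stresses as the cause of most calls. A biological difference between the cultivars stays open and was not tested apart from the arrays.

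The changes under heat and drought spread more in Plainsman V (SD of the log2 folds 0.81 against 0.69), and the major axis slope of Plainsman V on Capelle Desprez was 1.22 over all tested probes. Ordinary regression, which scatter in its predictor lowers, gave 0.96 for Plainsman V on Capelle Desprez and 0.69 the other way. Dim or saturated spots were argued against, since the major axis slope was 1.25 among the 10002 probes that were well above background and unsaturated in both channels of all 4 arrays. The slope was 1.29 on slide 2 and 1.1 on slide 3, so a deviating array on slide 2 cannot be told apart from a cultivar difference with 2 slides. After scale normalization the slope was 1.04, by the construction of that setting. A uniform difference in scale between the arrays may therefore remain, as may a stronger response of Plainsman V.

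Other splits of the 8 arrays into 4 and 4 were fitted with the group means and the dye term, leaving out terms that the split itself repeated. Since the numbers pair the arrays, the real splits were compared with those that have 2 arrays of each replicate number on each side. These are 18, too few for a share under 0.05. For heat and drought minus drought, 1 of the 18 called as many probes, the real one (4574, highest other 130 at the split that crosses cultivar with stress). For the cultivar difference 3 of the 18 did, the real one with 125, the crossed one with 130 and the split by stress with 4574. Splits within groups leave 1 residual degree of freedom less, so their counts are not fully comparable. The split by replicate number, outside the 18, called 2406. Both stress and replicate number are thus structures of these arrays beside the cultivar. Simpler models were counted first. With dye and stress terms alone the cultivar split called 0 probes (limma, 1380 at an unadjusted p under 0.05).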

How the results depend on the processing

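The directions of the 32 named results were kept under every alternative. The naming rule took the largest folds and, for the responses, 1 sign on every array, so kept directions are little support. Of the 32, 18 passed the threshold under every alternative in which the probe was tested. The other 14 missed it under at least 1, and these were drought results or cultivar differences. From Feature Extraction's processed signals 10 missed it, without the dye term 5 and after scale normalization 4. All named average cultivar differences missed it from the processed signals and after scale normalization, where 0 probes passed. Heat and drought averaged over both cultivars stayed within 1.5 times its count of 6444 under every alternative run. The fits on 4 arrays of 1 stress, the GC correction, slide as a fixed block and the scaling of the heat and drought arrays were chosen after the data were examined. The tests of the gene lists were not run, since no probe carries a description. Signal over background limits the falls to the levels given as bounds. For each count below, the cause of the change was not tested unless stated.

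For drought in Capelle Desprez (327) the count was 67 from Feature Extraction's processed signals and from the series matrix, 942 after scale normalization between arrays, 52 with no replicate block (no dye term), 111 with slide as a random block and 2269 from the drought arrays alone. For drought in Plainsman V (180) these were 0 and 0 (2322 unadjusted in limma), 1251, 24, 58 and 1888, and 300 with the filter on all 8 arrays. For drought averaged over both cultivars (1244) they were 672 and 672, 2554, 262, 144 and 3519. Fits on the drought arrays alone leave 1 residual degree of freedom per probe, and the dye term absorbs the difference between the slides there. For heat and drought, the count without the replicate block was 2583 in Capelle Desprez (4373), and after scale normalization it was 3361 in Plainsman V (5443). For heat and drought minus drought (4574) it was 2784 without the replicate block. For the average cultivar difference (125) the count was 0 from the processed signals and from the series matrix (2066 unadjusted), 0 after scale normalization (1685 unadjusted), 194 with median centring, 26 without the replicate block, 465 with slide as a random block and 493 with slide as a fixed block. Under heat and drought (680) it was 246 and 246, 51 after scale normalization, 236 without the replicate block, 1341 and 1538. Under drought (0) it was 356 from the drought arrays alone and 1 with slide as a fixed block, and 0 in the other settings, where 438 to 1712 probes passed unadjusted in limma. The paired fit, with the dye term as the block, is the main one, and dropping it changed no other count by over 1.5 times.

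Leaving out 1 array leaves its group with 1 array, which is assumed to vary like the others. The counts then ranged from 1 to 155 for drought in Capelle Desprez (155 without a Plainsman V heat and drought array, 152 without one of Capelle Desprez, 1 without either Plainsman V drought array or Capelle Desprez replicate 2, 11 without its replicate 1). For drought in Plainsman V they ranged from 0 to 182, with 0 without either of its own arrays (758 and 1050 unadjusted), 84 without a Capelle Desprez heat and drought array and 104 without one of Plainsman V. For drought averaged they ranged from 1 (without Plainsman V replicate 1) to 954, with 2, 541 and 136 without Plainsman V replicate 2 and Capelle Desprez replicates 1 and 2. For heat and drought they ranged from 1409 to 4508 in Capelle Desprez (1409 and 2134 without its replicates 2 and 1), from 2836 to 5539 in Plainsman V (2836 and 3192 without its replicates 1 and 2), and from 4703 to 6587 averaged. For heat and drought minus drought they ranged from 2694 to 4139, the lowest being 2694 and 2799 without Plainsman V drought replicates 1 and 2. For the average cultivar difference they ranged from 0 to 37: 0 without either Plainsman V drought array (1329 and 1325 unadjusted) or Capelle Desprez heat and drought replicate 2 (1758 unadjusted), 33 and 28 without Capelle Desprez drought replicates 1 and 2, 16 without Capelle Desprez heat and drought replicate 1, and 25 and 37 without Plainsman V heat and drought replicates 1 and 2. Under heat and drought the difference ranged from 109 to 644: 154 and 109 without Capelle Desprez replicates 1 and 2, 112 and 133 without Plainsman V replicates 1 and 2, and 160 without a Plainsman V drought array. Under drought alone it stayed at 0.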

Other observations

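The tests in this part, the GC correction included, were chosen after the data were seen, although the bound for the drought calls after that correction was set before their count was known.

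Control seeds of the cultivars differed in their own right. In the control channels, with slide as a block, 392 probes were higher in Plainsman V and 336 lower (limma, adjusted p under 0.05), and 350 of these 728 differed at least 2-fold. The difference between the cultivars correlated at 0.84 over probes between replicates 1 and 2. Of the 18 splits with 2 arrays of each replicate number on each side, 1 called as many, the real one (728, highest other 4), and 18 are too few for a share under 0.05. The split by replicate number, outside the 18, called 882 with slide and cultivar terms, 376 with slide terms alone and 914 without a slide term, and it coincides with the dye orientation. Whether the drought and the heat and drought arrays of 1 replicate shared a control extract is not stated, and with their control channels averaged 1616 probes passed (4688 at an unadjusted p under 0.05).

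A hypothesis was that heat and drought narrowed these differences. The control difference on the drought arrays of 1 replicate was set against the cultivar difference of the response on the heat and drought arrays of the other replicate, so that no control was shared if each replicate had its own. Of the probes with a control difference of 2-fold or more and with both channels well above background on the heat and drought arrays, 407 of 731 (55.7%) and 355 of 618 (57.4%) responded in the narrowing direction. This lies between the 50% of no relation and the 60% set for the hypothesis, so a partial convergence stays open. Over all tested probes the correlations were 0.1 and 0.05. Probe 229750, picked after its values were seen, narrowed from log2 control signals of 12.79 in Capelle Desprez and 8.42 in Plainsman V to stressed signals of 10.27 and 10.

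Probe 147223, with the highest fitted difference between the stresses, reads as a glutamine-rich peptide, a composition known from the storage proteins of the wheat endosperm. A hypothesis was that transcripts for glutamine- and proline-rich peptides rose under heat and drought. Probe 147223 itself, with 7 glutamines and 1 proline, fell outside the class tested. Of the tested probes, 27 had an open sense frame with at least 6 glutamines and 2 prolines, and 14 had such a frame only on the antisense strand and served as the comparison. The median log2 fold was 0.32 for the sense frames and -0.11 for the antisense frames, a difference of 0.43 (two-sided permutation p = 0.00618 with 100000 permutations). Of the 27 sense probes 16 rose and 1 fell, and of the 14 antisense probes 3 rose and 3 fell. The sense medians were 0.40 in Capelle Desprez and 0.25 in Plainsman V. The hypothesis was drawn from large rises in these same data, and the permutation treats the probes as independent. Probes of 1 gene family can cross-hybridize and are not independent, and no probe carries a gene name. The p-value is therefore no independent support, and a rise of glutamine- and proline-rich storage protein transcripts stays open. The limits of 6 and 2 were set after the class sizes had been seen.

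The drought log ratios of the 2 replicates did not correlate over probes (0.03 in each cultivar), whereas drought arrays of different cultivars on the same slide did (0.68 and 0.69). After subtracting the dye term of the heat and drought arrays the replicates correlated at 0.24 in Plainsman V and 0.02 in Capelle Desprez. The error of that term enters both cultivars on a slide alike and the 2 replicates with opposite signs. It therefore raises correlations within a slide and lowers those between replicates. The test thus cannot decide whether a dye effect common to all slides was the whole cause. Removing a trend with probe GC content left them at no more than 0.06. Both cultivars shared something on a slide, with correlations of 0.66 and 0.67 between cultivars after the dye correction. Slide, scan batch, a dye effect (common or particular to a slide) and a difference between the replicate sets of plants are confounded in it. A drought response that differed between the sets may be present as well.

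Log ratios under drought fell with the GC content of the probe in Capelle Desprez (Spearman's rho -0.30 over probes) and not in Plainsman V (-0.02). Dye-linked labelling is argued against, because rho was negative in both dye orientations in Capelle Desprez (-0.15 and -0.26). The trend did not make most of the drought calls there, since 289 of the 327 still passed after a GC correction, which called 339 in all. Differences in RNA quality between the Capelle Desprez extracts and a biological shift stay open, and neither was tested.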
